A study of Mus musculus with 2 samples.

How the data were processed

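Single-cell RNA sequencing had been made from CD45-positive cells that were sorted from subcutaneous B16F10 tumours, with 2 libraries, 1 per group. The control library came from mice given untreated bone-marrow-derived macrophages and the IL4 library from mice given IL-4-treated ones, per the labels. The grouping follows the treatment given among the sample characteristics. The protocol field names IL-4-treated macrophages for both libraries, so the labels are not in full accord. The number of animals per library is not given in the sources used here. The authors deposited whole-number UMI counts per gene and barcode, made with Cell Ranger 7.2.0 on the mm10 build per the submitters' processing notes. The annotation release is not given in the sources used here. The deposited counts hold 32285 genes and only barcodes of at least 500 UMIs. No deposited cell annotation was used here.

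From these counts, barcodes with at least 500 UMIs, at least 250 genes and at most 10% mitochondrial UMIs were kept, which left 8936 of 8994 control barcodes (99.4%) and 13762 of 13873 IL4 barcodes (99.2%). Below the gene minimum lay 10 and 5 barcodes and above the mitochondrial limit 57 and 111, and these groups overlap. Scrublet (in scanpy, expected rate 0.06) called 1 doublet in the control and 0 in the IL4 library. At these numbers of cells the caller has not worked, and most doublets within or between similar classes remain in the data. Cells were scaled to 10000 UMIs and log-transformed. Genes seen in at least 3 cells were kept, and 2000 variable genes, without mitochondrial, ribosomal, immunoglobulin, T cell receptor variable and sex-linked genes, gave 30 principal components. A graph of 15 neighbours was clustered with Leiden at resolution 1, without batch integration, into 20 clusters. T and NK clusters were clustered again at resolution 0.5.

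Cell names came from 23 marker lists fixed before the data were examined. A marker counted as raised in a cluster at 1.5-fold over the other clusters, and a name needed at least 3 raised markers and a lead of at least 2 over the next name. Clusters without such a lead stayed unnamed, among them one led by Arg1 and hypoxia genes, one led by interferon-stimulated genes, one led by Retnla and Ear2, and one of low UMI number. Outside the T and NK clusters, a cluster with at least 6 cycling markers raised was named cycling, whatever its other markers. T cell subclusters whose Cd4 and Cd8a levels lay within 2-fold were left undivided. The macrophage-like, monocyte-like and unnamed myeloid clusters together held 66.2% of control and 64.1% of IL4 cells. In the T and NK clusters, barcodes with more than 20 UMIs per 10000 in 8 myeloid genes (C1qa, C1qb, C1qc, Apoe, H2-Aa, H2-Ab1, H2-Eb1 and Cd74) were set apart as mixed, a limit chosen after the clusters had been seen. Between 15 and 25 per 10000 lay 65 control and 168 IL4 barcodes. A subcluster of 43 control and 96 IL4 barcodes within that limit was also counted as mixed. It had 10 macrophage markers raised and 0 T cell or NK markers.

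Shares of cells carry exact Clopper-Pearson 95% binomial intervals, and their differences Newcombe intervals. For each class, UMIs were summed per library and scaled by the UMI total of the class (CPM), with exact Poisson intervals. Macrophage-like cells held 16466110 control and 23746500 IL4 UMIs, and CD8 T cell-like cells 1069871 and 1755657, so the precision in CD8 T cell-like cells is lower. The log2 ratio is that of IL4 CPM plus 1 over control CPM plus 1. Folds were taken without this pseudocount, with exact intervals from the counts. From 25 gene lists fixed before the data were examined, members with at least 20 UMIs gave the list median, its interval from 2000 Poisson redraws, and its percentile among 10000 random lists of the same size matched on mean expression. A percentile describes these libraries and is not a test. A member counts as higher or lower at 1.5-fold on the scale with the pseudocount. Lists were to be described in classes with at least 200 cells per library. Those of the CD8 T cell-like, NK-like and neutrophil-like classes, which have fewer in at least 1 library, are given as well, and those computed in other small classes are not described. Shares of cells with a UMI were taken after thinning to 1000 UMIs, which left out 6 control and 10 IL4 macrophage-like cells.

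Named genes were those with the 10 highest and 10 lowest log2 ratios among genes with at least 50 UMIs in the class, at least 20 CPM in the higher library and at least 25% of the gene's highest class CPM. To these came up to 4 members per list with the largest absolute ratio, and fixed genes of macrophages (Smyd5, Il4ra, Cd74, H2-Ab1, H2-K1, B2m, Mrc1, Arg1, Ciita) and CD8 T cells (Cd8a, Ifng, Gzmb, Prf1, Pdcd1, Tcf7, Mki67). Mitochondrial, ribosomal, receptor, immunoglobulin, haemoglobin and predicted genes were left out by that rule. Barcodes were divided by Xist and the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty into those with Xist only, Y-linked transcripts only, both or neither. Gene positions were taken by gene identifier from the GENCODE annotation of the mm10 (GRCm38) build.

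The gene and list steps were tested on simulated counts with 200 genes changed by known folds. In the macrophage comparison (11555 genes) and in the CD8 comparison (6520 genes) 100% of genes changed by a log2 of 1 and of 2 came out in the right direction. Counting intervals covered the true value for 98% and 95% of them in macrophages and for 95% and 98% in CD8 T cells. The simulated counts were Poisson draws from the class totals, as the intervals assume, without variation between cells or animals. This coverage therefore does not show that the intervals hold for genes whose UMIs sit in few barcodes. In all, 15 alternatives fixed before the data were examined and 10 chosen later were run on the filters, clustering, scaling and choice of barcodes. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scanpy 1.11.5, igraph 0.11.9, scikit-learn 1.9.0, statsmodels 0.14.6 and matplotlib 3.10.9.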

Results

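Single-cell RNA sequencing had been run on CD45-positive cells, that is, on leukocytes, sorted from subcutaneous B16F10 tumours. B16F10 is a transplantable mouse melanoma line. The mice had been given bone-marrow-derived macrophages, either untreated (control) or exposed to IL-4, the cytokine that drives alternative macrophage activation (IL4). There were 2 libraries, 1 per group. The control library held 8994 barcodes and 95499107 UMIs, with a median of 9156.5 UMIs and 2729 genes per barcode. The IL4 library held 13873 barcodes and 133151428 UMIs, with medians of 8213 UMIs and 2584 genes. With 1 library per group the differences have no replicate check, no test was run, and each interval covers counting error only. They compare these libraries, and differences between animals are part of them. Both libraries held cells with Xist, the RNA that silences an X chromosome in female cells, and cells with transcripts of Y-linked genes. Among barcodes with transcripts of 1 kind only, Y-linked ones made up 36.8% (exact 95% interval 35.6% to 37.9%) in the control and 10.9% (10.3% to 11.5%) in the IL4 library. Values within Xist-only and Y-only barcodes are therefore given beside many of the main ones.

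The first comparison concerned which leukocytes the tumours held after either transfer. NK-like cells, the innate killer lymphocytes, made up 1.95% (1.67% to 2.26%, 174 cells) of kept control cells and 3.51% (3.21% to 3.83%, 483 cells) of IL4 cells, a difference of 1.56 points (1.14 to 1.98). Neutrophil-like cells went the other way, from 4.61% (4.19% to 5.07%) to 1.18% (1.01% to 1.38%), and B cell-like cells from 1.04% to 0.320%. Macrophage-like cells, the tissue phagocytes, made up 17.98% (17.2% to 18.8%) and 20.4% (19.7% to 21.1%), 2.41 points apart (1.37 to 3.45). All T cell-like cells together made up 2.09% (187 cells) and 2.33% (321 cells), and their difference of 0.24 points had an interval from -0.16 to 0.62 that spans 0. CD8 T cell-like cells, the cytotoxic T cells, made up 0.683% (0.523% to 0.876%, 61 cells) and 0.945% (0.790% to 1.12%, 130 cells). Their shares were 0.745% and 0.795% among Xist-only and 0.961% and 2.44% among Y-only barcodes, and those of all T cell-like cells 2.63% and 2.18%, and 2.20% and 4.32%.

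Among the dendritic cells, which prime T cells, the mature migratory DC-like class made up 4.11% and 4.93% of cells, 0.82 points apart (0.26 to 1.36). The cross-presenting conventional DC type 1-like class made up 2.70% and 3.10%. The conventional DC type 2-like class made up 10.4% and 10.2%. Plasmacytoid DC-like cells, producers of type I interferon, made up 0.425% (38 cells) and 0.945% (130 cells). Monocyte-like cells made up 20.6% and 18.9%, a difference that turned to 1.63 points in favour of the IL4 library at a clustering resolution of 2.0. Regulatory T cell-like cells made up 0.224% (20 cells) and 0.116% (16 cells). Clusters left without a name held 27.7% and 24.9%. Among them, one led by Arg1 and hypoxia genes held 10.9% (971 cells) and 3.11% (428 cells), a size that the level of those genes can itself set, and one led by predicted genes 1.33% and 4.20%. Cells of a cycling cluster whose types were not divided made up 1.24% in each library (111 and 170 cells). This cluster had 10 conventional DC type 1 markers raised, against 6 for the next name. The conventional DC type 1-like shares leave its cells out.

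The order of the NK and neutrophil shares was the same within each sex. NK-like cells made up 2.21% of control and 3.69% of IL4 cells among Xist-only barcodes and 2.04% and 3.91% among Y-only barcodes. The macrophage-like share did not keep its order. It was 22.6% and 21.7% among Xist-only and 14.7% and 19.7% among Y-only barcodes, its difference ranged from -0.86 to 9.05 points over the alternatives tried, and the sort and the recovery of cells can set any of these shares. A further 5.21% of control and 7.99% of IL4 cells sat in T and NK clusters but carried myeloid transcripts. They were left out of the T and NK classes. Counted with them, T and NK clusters held 9.27% (8.67% to 9.89%) and 13.9% (13.4% to 14.5%) of cells.

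**Figure D1:**
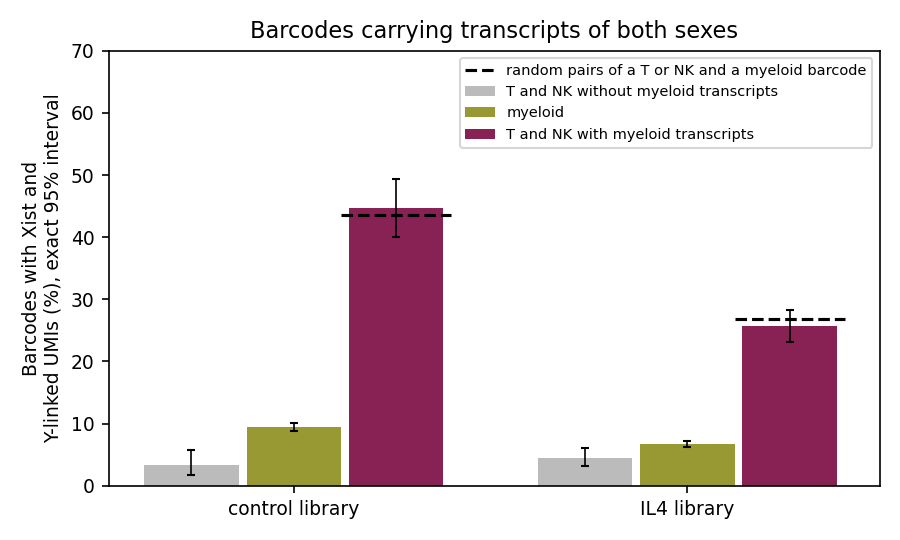
Percent of barcodes with both Xist and Y-linked UMIs (vertical axis, exact 95% binomial intervals) in T and NK barcodes without myeloid transcripts, in myeloid barcodes and in T and NK barcodes with myeloid transcripts. Dashed lines mark random pairs of a T or NK and a myeloid barcode: 44.6% of the control barcodes with myeloid transcripts carried both, against 43.5% for random pairs.

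**Figure D2:**
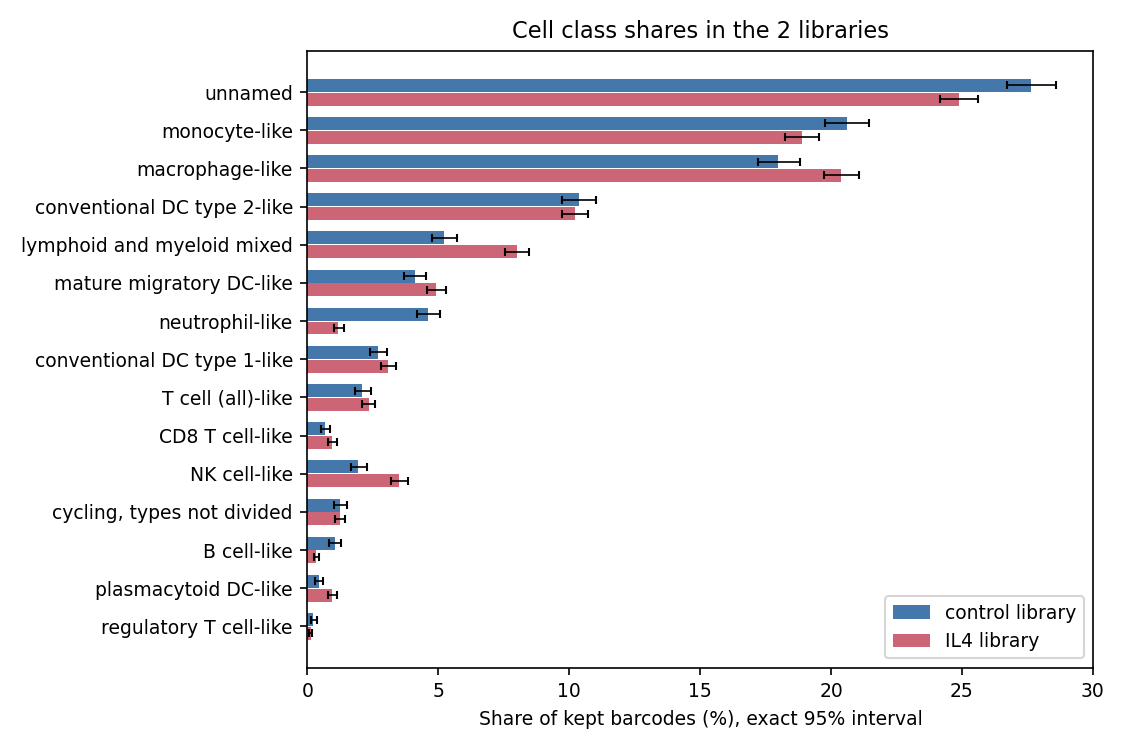
Share of kept cells (percent, horizontal axis) in each cell class for the control and IL4 libraries, with exact 95% binomial intervals that cover counting error only. The NK-like share was 1.95% in the control and 3.51% in the IL4 library, and the neutrophil-like share 4.61% and 1.18%.

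The second comparison asked how macrophages in the tumour differed, since the series concerns IL-4 and antigen presentation by macrophages. Transferred and host macrophages were not told apart here, so the values cover both together. Inflammatory genes were higher in macrophage-like cells of the IL4 library. List members are counted as higher or lower at a ratio of CPM plus 1 of at least 1.5-fold. Of 16 NF-kB inflammatory genes, targets of the transcription factor that drives acute inflammation, 11 were higher and 0 lower, with a median log2 ratio of 0.75 (counting interval 0.73 to 0.76). The neutrophil chemoattractant Cxcl1 stood at 279 CPM (271 to 287) in the control and 698 CPM (687 to 709) in the IL4 library, a fold of 2.51 (2.43 to 2.59). The cytokine genes Il1a and Tnf were 2.32-fold (2.12 to 2.54) and 1.92-fold (1.86 to 1.98) higher, and Ccl4, which attracts lymphocytes and monocytes, was 1.90-fold higher (1.88 to 1.91). The medians of the T cell-recruiting chemokines (0.57, 0.50 to 0.66, 5 of 11 higher and 0 lower) and the type I interferon response genes (0.52, 0.48 to 0.64, 7 of 15 higher and 0 lower) were also above 0.

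Among single antiviral genes of that interferon list, Isg15 was 1.90-fold (1.85 to 1.96), Oasl1 1.83-fold (1.78 to 1.89), Ifit3 1.86-fold (1.69 to 2.05) and Irf7, an interferon regulatory transcription factor, 1.79-fold (1.70 to 1.88) higher. The highest ratio among the genes that the naming rule covers was that of Il10, which encodes an anti-inflammatory cytokine. It stood at 88.7 CPM (84.2 to 93.3) and 272 CPM (265 to 278), a fold of 3.06 (2.90 to 3.25). After thinning each cell to 1000 UMIs, 8.24% (6.94% to 9.70%) of control and 20.6% (19.1% to 22.1%) of IL4 macrophage-like cells had an Il10 UMI, against 25.1% and 46.2% unthinned. The thinned share in T cells not divided into CD4 and CD8 was 2.02% and 3.09%. Their median depths were 5879 and 4869 UMIs, against 9080 and 7440 UMIs in macrophage-like cells. Areg, an EGF receptor ligand, was 2.70-fold (2.51 to 2.90) higher, and the interferon-inducible Ifi205 stood at 66.4 and 166 CPM. Tnfsf9, the ligand of the costimulatory receptor 4-1BB, was 2.04-fold higher (1.89 to 2.21). The other genes with the highest ratios were Plagl1 (a fold of 2.45), Olr1 (2.24), a scavenger receptor gene, Arl5c (2.14) and Cd72 (2.10).

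Each of these 3 lists lay at percentile 100 of 10000 random lists matched on expression. The median over all genes was -0.11. In the same cells the lists of T and NK cell genes also lay above 0 at percentile 100, the cytotoxic effector list with a median of 0.49 (0.22 to 0.52, 4 of 15 higher and 0 lower) and the exhaustion and inhibitory receptor list with one of 0.41 (0.26 to 0.46). Ccl3, Ccl4 and Ccl5 belong to both the cytotoxic and the chemokine list, and Ccl5 stood at 148 and 416 CPM. The ratio was above 1 for 12 of the 15 cytotoxic genes. Gzma and Nkg7, killer cell genes chosen after their values were seen, stood at 9.17 and 6.91 CPM and at 6.56 and 6.91 CPM. The cytotoxic median was 0.43 in Xist-only and 0.25 in Y-only barcodes. The dissociation stress list, a sign of handling, had a median of 0.23 (0.22 to 0.25) at percentile 99.7 in these cells, with 1 of 17 members higher and 4 lower. Within Xist-only and Y-only barcodes the medians were 0.76 and 0.95 for NF-kB genes, 0.44 and 0.48 for type I interferon genes, and 0.64 and 0.25 for chemokines. The class was made of 3 clusters. One led by Cxcl1, Il1a and Il10 held 516 control and 1588 IL4 cells, one led by Spp1, Ccl24 and Lpl 227 and 98, and one led by Ccl8, Cbr2 and C1q genes 864 and 1121. With the control clusters weighted as in the IL4 library, the NF-kB median was 0.37, the type I interferon median 0.44 and the chemokine median 0.60, and 4 of the 16 NF-kB genes were higher. Within the clusters led by Cxcl1, by Spp1 and by Ccl8 the NF-kB medians were 0.19, 0.21 and 0.82, with 2, 1 and 11 genes higher, the type I interferon medians 0.43, 0.52 and 0.42, and the chemokine medians 0.46, 0.20 and 0.82. The log2 ratio of Cxcl1 then moved from 1.32 to 0.61, that of Il1a from 1.19 to 0.50, and that of Il10 from 1.60 to 1.26.

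**Figure D3:**
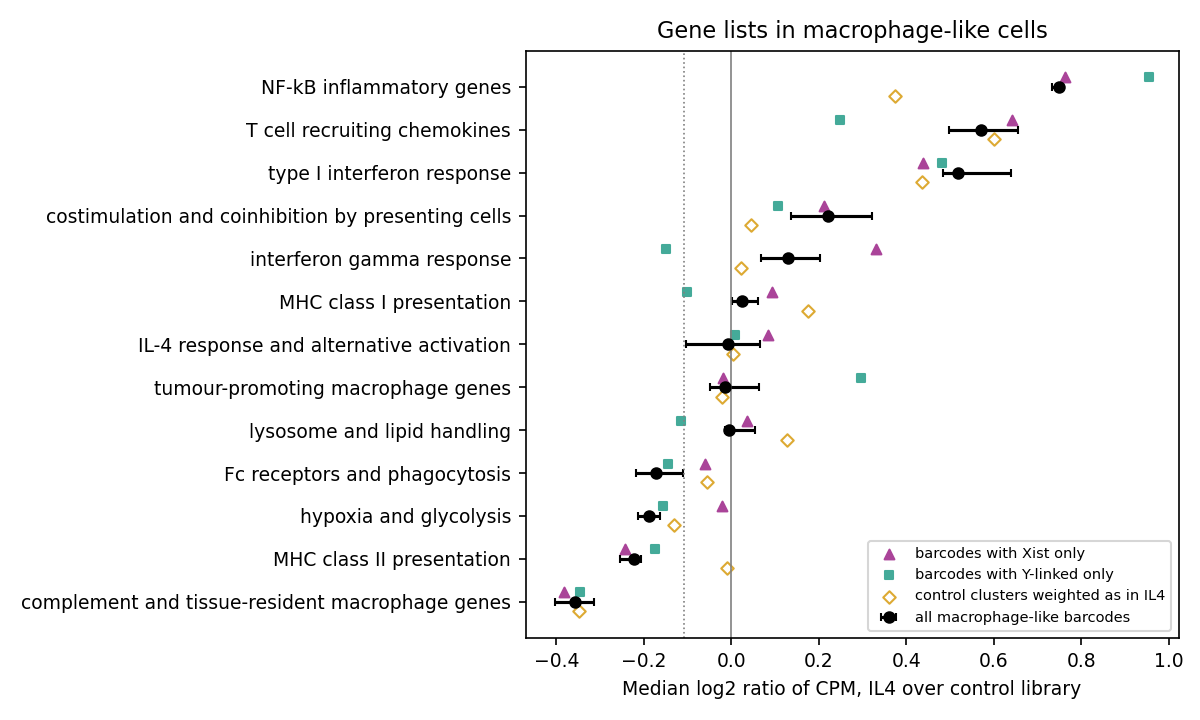
Median log2 ratio (IL4 over control, horizontal axis) of 13 of the fixed gene lists in macrophage-like cells, with counting intervals, for all barcodes (circles), Xist-only (triangles) and Y-only barcodes (squares), and with the control clusters weighted as in the IL4 library (diamonds). Of the lists drawn, the NF-kB list had the highest median, 0.75, and the complement and tissue-resident list the lowest, -0.36.

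Antigen presentation genes differed less. MHC class II presentation genes, which display peptides to CD4 T cells, had a median log2 ratio of -0.22 (-0.26 to -0.21), at percentile 1.16 of random lists. Of the 15 members, 1 was at least 1.5-fold lower and 0 higher. That member was Ciita (chromosome 16, 10480059 to 10528418, ENSMUSG00000022504), the master transcriptional activator of MHC class II, at 67.7 CPM (63.8 to 71.8) and 42.9 CPM (40.3 to 45.6), a log2 ratio of -0.65. Cd74 (chromosome 18, 60803848 to 60812652), the invariant chain, stood at 5648 and 4739 CPM, and H2-Ab1 (chromosome 17, 34257689 to 34269419), a class II beta chain, at 2575 and 2211 CPM. The peptide-loading gene H2-DMb1 had a log2 ratio of -0.55, H2-DMb2 -0.45 and H2-Ob 0.51. In MHC class I presentation genes, which display peptides to CD8 T cells, 0 of 18 members were 1.5-fold higher or lower, with a median of 0.02 (0.00 to 0.06). H2-K1, a class I heavy chain, stood at 1070 CPM (1054 to 1086) and 1289 CPM (1275 to 1303), a log2 ratio of 0.27, and its partner B2m had a log2 ratio of 0.03. The class I members with the lowest ratios were the peptide trimmer Erap1 (-0.55) and the chaperones Canx (-0.38) and Pdia3 (-0.29).

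The class II median was -0.24 in Xist-only and -0.17 in Y-only barcodes, and it ranged from -0.24 to -0.03 over 15 other choices of filter, clustering and scaling fixed before the data were examined. It was -0.01 (-0.05 to 0.03) when the control clusters were weighted as in the IL4 library, and within the clusters led by Cxcl1, by Spp1 and by Ccl8 it was -0.01, -0.05 and 0.00. The weighted log2 ratio of H2-Ab1 was 0.02, that of Cd74 -0.05 and that of Ciita -0.50, short of 1.5-fold. The class I median was 0.09 in Xist-only and -0.10 in Y-only barcodes and 0.18 when weighted. Costimulatory and coinhibitory genes had a median of 0.22 (0.14 to 0.32), with 4 of 14 higher and 1 lower, and 0.04 when weighted. Interferon gamma response genes, induced by the main T and NK cell cytokine, had a median of 0.13 (0.07 to 0.20), with 4 of 18 higher and 0 lower. It was 0.33 in Xist-only and -0.15 in Y-only barcodes, 0.02 (-0.05 to 0.09) when weighted and -0.12 at a clustering resolution of 0.5.

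Smyd5 (chromosome 6, 85431989 to 85446435, ENSMUSG00000033706), the SMYD family methyltransferase named in the series title, was thinly covered. Macrophage-like cells held 168 control UMIs and 157 IL4 UMIs, or 10.2 CPM (8.72 to 11.9) and 6.61 CPM (5.62 to 7.73), a log2 ratio of -0.56. After thinning, 0.937% of control and 0.751% of IL4 macrophage-like cells had a Smyd5 UMI, against 8.96% and 5.13% unthinned. In undivided T cells the thinned shares were 1.01% and 0% (0 of 162 cells, exact upper limit 2.25%), against 4.04% and 3.07% unthinned. With so few cells carrying a UMI, thinned shares of this gene cannot be read as a level of expression. The log2 ratio was -0.24 among Xist-only and -0.94 among Y-only barcodes. The list of SMYD family and related histone methyltransferases had a median of 0.02 (-0.13 to 0.08), with 0 of 10 higher or lower. Without the added 1 CPM, Smyd5 was 1.54-fold lower.

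Genes of the IL-4 response and of tissue-resident macrophages included the lowest ratios. In the IL-4 response list, 4 of 20 genes were higher and 4 lower, with a median of -0.01 (-0.10 to 0.07). Retnla, a classic marker of alternative activation, stood at 141 CPM (135 to 147) and 19.4 CPM (17.6 to 21.2), a log2 ratio of -2.80. The lectin genes Mgl2 and Clec10a had log2 ratios of -1.87 and -0.81, and the eosinophil attractant Ccl24 -1.66. Arg1, which consumes arginine, stood at 336 and 323 CPM, Mrc1, the mannose receptor gene, at 569 and 423 CPM, and Il4ra, the IL-4 receptor gene, at 129 and 140 CPM. The complement and tissue-resident list had a median of -0.36 (-0.40 to -0.31), with 5 of 13 members lower and 0 higher, at percentile 0. Within the clusters led by Cxcl1, by Spp1 and by Ccl8 it was -0.01, 0.10 and -0.46, with 0, 0 and 6 members lower. Its member Lyve1, a hyaluronan receptor gene, stood at 23.6 CPM (21.3 to 26.1) and 3.41 CPM (2.71 to 4.24).

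Spp1, which encodes osteopontin, stood at 800 CPM (786 to 814) and 277 CPM (270 to 283). The heat-shock genes Hspa1b and Hspb1 had log2 ratios of -1.33 and -1.61, and their cochaperone Bag3 -1.20. The remaining genes with the lowest ratios were Fcrls (-1.59), Igfbp4 (-1.40) and Qpct (-1.18). Among the other lists, hypoxia and glycolysis genes had a median of -0.19, Fc receptors and phagocytosis -0.17, tumour-promoting genes -0.01, and lysosome and lipid handling -0.01. The tumour-promoting list had 3 of 13 members higher and 3 lower, with a median of 0.30 (0.19 to 0.37) in Y-only barcodes, 0.40 within the cluster led by Ccl8 and up to 0.49 over the choices fixed before the data were examined. The Fc receptor median reached 0.02 over those choices. The hypoxia median was -0.02 (-0.06 to 0.01) in Xist-only barcodes and turned to 0.11 with variable genes chosen within each library. Over the macrophage-like, monocyte-like and unnamed myeloid clusters together, which take in the one led by Arg1, the hypoxia median was -0.36 (-0.38 to -0.36) and Arg1 stood at 421 and 237 CPM. In Y-only barcodes the log2 ratio of Retnla was 0.23, against -3.28 in Xist-only barcodes, and that of Arg1 was 0.26. The complement list kept its sign, at -0.38 and -0.35. With the clusters weighted, the log2 ratio of Spp1 was -0.47, that of Ccl24 -0.76, that of Mgl2 -1.01, that of Retnla -2.58 and that of Arg1 -0.61.

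**Figure D4:**
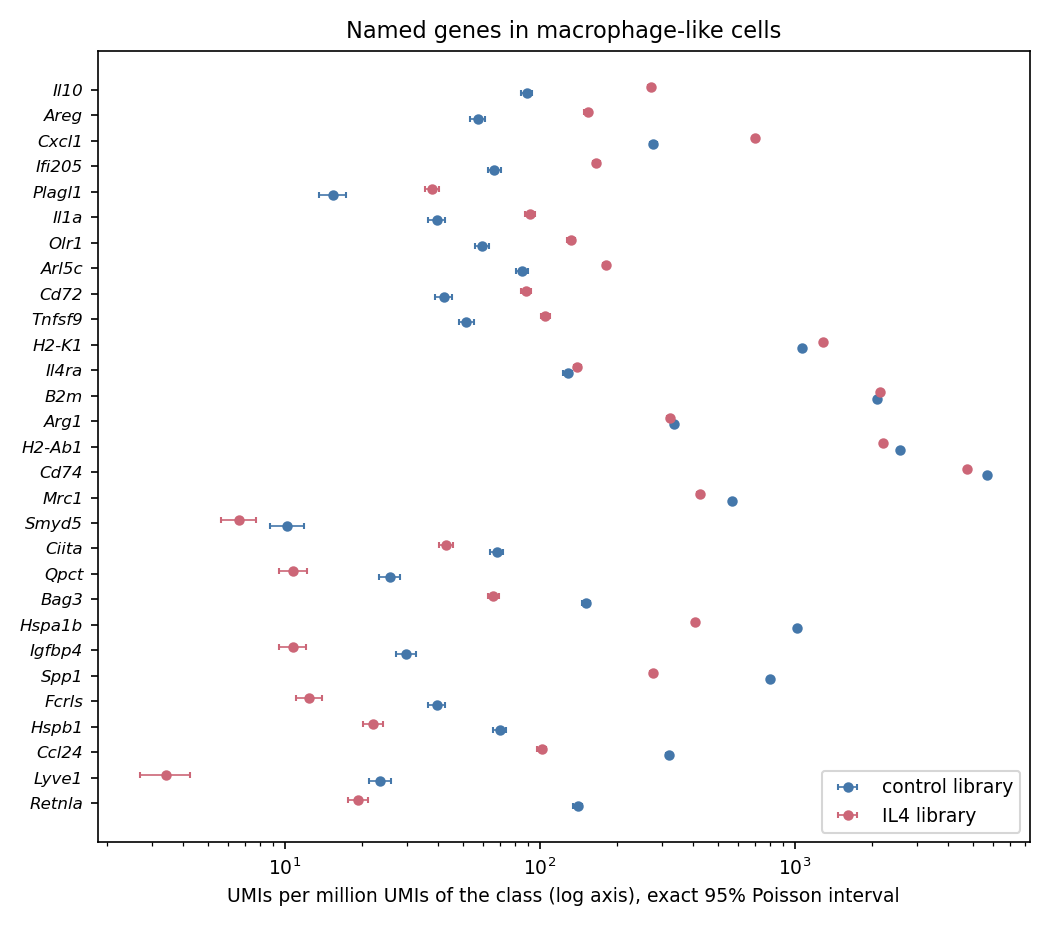
Level of named genes in macrophage-like cells (CPM, on a log axis) in the control and IL4 libraries, with exact 95% Poisson intervals. Il10 stood at 88.7 and 272 CPM and Retnla at 141 and 19.4 CPM.

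The third comparison concerned CD8 T cell-like cells, since the series asks about T cells that restrain the tumour. It rests on 61 control cells (median 16702 UMIs) and 130 IL4 cells (median 10559 UMIs). These cells formed a single subcluster, with 8 cycling markers raised over the other T and NK subclusters. The T cell cluster with Cd8a among its leading genes held 429 control and 875 IL4 barcodes before mixed ones were set apart. Of 19 cytotoxic effector genes, 1 was at least 1.5-fold higher and 5 lower, with a median log2 ratio of -0.07 (-0.22 to 0.01) at percentile 9.46. Gzmb, the granzyme that triggers apoptosis in target cells, stood at 1337 CPM (1268 to 1408) and 1331 CPM (1277 to 1386). Prf1, which encodes the pore-forming perforin, stood at 479 CPM (439 to 523) and 299 CPM (274 to 326), and Ifng, the gene of interferon gamma, at 558 CPM (514 to 605) and 373 CPM (345 to 402). The exhaustion and inhibitory receptor list had a median of -0.18 (-0.32 to -0.06) at percentile 0.24, with 3 of 14 lower and 0 higher. Its inhibitory receptor genes Cd244a, Tigit, Cd160 and Pdcd1 had log2 ratios of -0.82, -0.68, -0.63 and -0.36, and the costimulatory receptor gene Tnfrsf9 -0.56. Over the choices fixed before the data were examined, the log2 ratio of Tigit reached -0.02, that of Pdcd1 -0.06, that of Ifng -0.03 and that of Prf1 -0.31. The ratio of Tnfrsf9 turned to 0.06 when cells were thinned to 1000 UMIs.

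The proliferation list had a median of 0.16 (0.03 to 0.28), with 2 of 19 higher and 0 lower. It was -0.18 with cells weighted equally, -0.13 with cells classed by marker levels without clusters and -0.22 with mixed barcodes kept. Mki67, a marker of dividing cells, stood at 240 CPM (212 to 271) and 379 CPM (351 to 409), and Birc5, needed for cell division, had the same log2 ratio of 0.65, which was -0.33 when cells were thinned to 1000 UMIs. Histone genes were among those with the highest ratios: Hist1h2ag had a log2 ratio of 2.07, Hist1h4c 1.52 and Hist2h2ac 1.51, and the cell-cycle regulator Mybl2 1.27. In that order these genes had 6, 11, 27 and 13 control UMIs. Hist1h2ak had a log2 ratio of 1.24, which turned to -0.49 when cells were thinned to 1000 UMIs. Ly6c2, a surface protein gene of effector and memory CD8 T cells, stood at 155 CPM (132 to 181) and 419 CPM (389 to 450). Naive and memory genes had a median of -0.06 and T cell receptor activation genes 0.19, and Tcf7, the transcription factor gene of stem-like T cells, had a log2 ratio of -0.88 on 38 and 33 UMIs. Of the 38 control UMIs 17 were in 1 barcode, and after thinning the ratio was 0.47. Interferon gamma response genes had a median of 0.29 (0.14 to 0.45), and type I interferon genes 0.21 (-0.12 to 0.51), with 0.58 in Xist-only and -0.74 in Y-only barcodes. Cd8a had a log2 ratio of -0.33.

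Several of the lowest ratios belonged to granzyme genes with most of their control UMIs in 1 barcode. Gzmd had 659 control UMIs, of which 645 were in 1 barcode, and 6 IL4 UMIs. Gzmf had 1067, of which 937 were in 1 barcode, and 152, and Gzmc 783, of which 656 were in 1 barcode, and 158. Gzmg had 193 UMIs in 1 control barcode and 0 in the IL4 library, where the exact upper limit was 2.10 CPM. Without the highest barcode of each library the log2 ratio of Gzme was 0.16, against -2.80 with it, while that of Gzmf in CD8 T cell-like cells was -1.31 and that of Gzmc in CD8 T cell-like cells -1.12, and the cytotoxic median was 0.05. In Y-only barcodes, of which there were 24 control and 30 IL4 ones, the log2 ratio was 3.04 for Gzmd, 1.17 for Gzmf and 0.35 for Gzmc. The 6 IL4 UMIs of Gzmd in the whole class lay in 2 barcodes, so its Y-only ratio rests on very few UMIs. The exhaustion median was -0.25 in Xist-only and 0.01 in Y-only barcodes, and it was 0.06 when cells were thinned to 1000 UMIs.

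In monocyte-like and DC-like classes the NF-kB, type I interferon and chemokine lists also lay above 0. The type I interferon median was 0.37 (0.30 to 0.45) in monocyte-like, 0.30 (0.26 to 0.37) in conventional DC type 2-like, 0.61 (0.50 to 0.76) in conventional DC type 1-like and 0.42 (0.30 to 0.48) in mature migratory DC-like cells. The monocyte-like class was made of a cluster of 893 control and 1672 IL4 cells, with a type I interferon median of 0.49, and one of 949 and 926 cells, with a median of 0.17. The NF-kB medians in the same order were 0.35, 0.42, 0.48 and 0.41, and the chemokine medians 0.43, 0.37, 0.37 and 0.54. MHC class II medians were -0.15, -0.05, -0.16 and -0.09, and MHC class I medians 0.03, 0.01, -0.09 and -0.04. The type I interferon median was 0.80 (0.68 to 0.92) in Xist-only and -0.35 (-0.59 to 0.55) in Y-only barcodes of conventional DC type 1-like cells, and 0.53 (0.46 to 0.61) and -0.22 (-0.29 to 0.03) in those of conventional DC type 2-like cells. The chemokine median of conventional DC type 1-like cells was 1.12 in Xist-only and 0.01 in Y-only barcodes, and their NF-kB median 0.57 and 0.19. In NK-like cells, of which the control library held 174, proliferation genes had a median of 0.40 (0.27 to 0.65), with 7 of 19 higher and 1 lower, and cytotoxic effector genes 0.08 (0.00 to 0.15). These cells formed 3 subclusters, of 150 control and 347 IL4 cells, of 11 and 86 cells led by Vegfa, and of 13 and 50 cells led by Gzmc with cycling genes raised. The proliferation median of NK-like cells was -0.06 when cells were classed by marker levels without clusters.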

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

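All tests in this part were chosen after the result was seen, except the one of free RNA as a source of the inflammatory genes. Transcripts of both sexes lay outside the measurement the comparisons use. Barcodes with Y-linked and no Xist UMIs made up 36.8% of single-sex barcodes in the control and 10.9% in the IL4 library, and they occurred in every larger class: 27.5% and 9.98% of single-sex macrophage-like, 34.9% and 11.5% of NK-like and 42.9% and 27.3% of CD8 T cell-like barcodes. In macrophage-like cells the MHC class I median was 0.09 in Xist-only and -0.10 in Y-only barcodes, which differ by 0.19 and have opposite signs; the difference was not tested.

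Of the barcodes in T and NK clusters, 56.3% in the control and 57.4% in the IL4 library also carried myeloid transcripts. Mixed barcodes held 2.499 times the median UMIs of unmixed ones in the library with the smaller ratio. This cannot decide on free RNA in the droplets, because the cell types in both sets can differ in depth. Unmixed CD8 T cell-like barcodes alone had medians of 16702 control and 10559 IL4 UMIs, against 17013.5 and 15439.5 in mixed ones. Of the mixed control barcodes, 44.6% (40.1% to 49.3%) carried transcripts of both sexes, against 3.31% of unmixed T and NK barcodes and 43.5% for random pairs of cells, and of the IL4 ones 25.6% (23.1% to 28.3%), against 4.41% and 26.8%. T or NK cells bound to the host's own myeloid cells would bring no cell of the other sex. The lower of the libraries' shares was 94.7% of random pairing, which argues against binding to host cells for most of these barcodes. Binding to transferred macrophages within the same animal could bring both sexes. These values cannot decide on it, because the sex of the macrophage donors is not given in the sources used here. A candidate explanation that these values leave open is that unrelated cells shared a droplet, for which the higher share was 103% of random pairing. Whether such sharing could be frequent enough for 56.3% and 57.4% of these barcodes was not tested. Myeloid barcodes carried transcripts of both sexes in 9.44% of control and 6.72% of IL4 ones. NK-like cells, which a transfer of macrophages would not bring, were also of both kinds. The control library held 95 Xist-only and 51 Y-only ones, and the IL4 library 371 and 48. This argues that each library combined cells of animals of both sexes, although the sources used here do not state pooling. Cells of separate animals that joined after pooling would give the same shares of barcodes with both kinds of transcripts. No other biological explanation was tested.

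The MHC class II list was lower in macrophage-like cells of the IL4 library, with a median of -0.22. A different mix of the sexes is argued against as the whole source, since the higher of the medians within Xist-only and Y-only barcodes was still -0.17. A different mix of macrophage-like clusters may account for it: with the control clusters weighted as in the IL4 library, the list median lay 0.074 above the weighted median of all genes. MHC class II genes were not kept out of that clustering, so the weighting can itself shrink a difference in these genes. It was not repeated on clusters made without list genes. Ciita, the member at least 1.5-fold lower before, had a log2 ratio of -0.50 under that weighting, which is short of 1.5-fold. Whether the mix of clusters itself differs through the transferred macrophages or through the animals stays open, as 1 library per group cannot separate them.

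The NF-kB, type I interferon and chemokine lists were higher in macrophage-like cells of the IL4 library. Free RNA was examined over the 39 list members of at least 20 UMIs with a higher CPM in IL4 macrophage-like cells. Their difference in CPM in undivided T cells was a median of 12.4% (6.28% to 21.7%) of that in macrophage-like cells. These T cells remained after barcodes with many myeloid UMIs had been set apart. The value can therefore be too low and does not exclude free RNA. A different mix of the sexes is argued against in macrophage-like cells, where the lowest of the 6 within-sex medians was 0.25. Harsher handling of the IL4 cells could not be decided, because the dissociation stress list lay above the median of all genes in 2 of 6 classes, of which macrophage-like cells are one. Free RNA, handling, the animals and the transfer stay open. The transfer was untested both as transferred cells within the class and as an effect on the host's cells, which were not told apart here.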

How the results depend on the processing

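The choices within sexes, on mixed barcodes, on doublet scores, with clusters weighted or joined and without the highest barcode were added after the data were seen, and the others were planned. In macrophage-like cells the NF-kB list (0.37 to 0.95), the type I interferon list (0.31 to 0.77), the chemokines (0.25 to 0.71) and the complement list (-0.67 to -0.17) kept their sign in all 24 alternatives. The MHC class II list (-0.24 to -0.01) did so only against 0. With control clusters weighted as in IL4, its interval (-0.05 to 0.03) spanned 0. Its weighted median of -0.01 lay above that of all genes, -0.08. The NK share (0.97 to 2.02 points) and the neutrophil share (-3.46 to -1.82 points) kept their sign in all 16 alternatives. Under the alternatives fixed before the data were examined, of 701 list values 478 stayed within counting error, 205 moved and 18 reversed. Of 121 share differences 104 stayed, 13 moved and 4 reversed, and of 390 gene values 246 stayed, 135 moved and 9 reversed. Under added ones the numbers were 268, 89 and 9 of 366, 71, 21 and 4 of 96, and 245, 130 and 15 of 390. A value was called reversed only where the interval of its main value did not take in both signs. Other changes of sign are among those that stayed or moved. Counting every change of sign, 72 list values, 9 share differences and 11 gene values turned under the alternatives fixed before the data were examined. Under the added ones 34, 7 and 17 turned. Below, lists are in macrophage-like cells unless another class is named, shares are IL4 minus control in points, and the cause was not tested unless stated. With a mitochondrial limit of 5% the macrophage share was -0.86 and the unnamed share 6.77, and the medians were -0.027 for MHC class II, 0.11 for class I, 0.096 for IL-4 response and 0.0088 for hypoxia. A limit of 20% gave a macrophage share of 3.61 and class II -0.076, and a minimum of 1000 UMIs and 500 genes class II -0.050 and class I 0.077. Keeping the doublet call changed 1 barcode, and the clusters it regrouped gave a macrophage share of 0.93, class II -0.12, class I 0.11, IL-4 response -0.13 and interferon gamma 0.25. Resolution 0.5 gave a macrophage share of 9.05, class II -0.13, IL-4 response 0.076 and interferon gamma -0.12. Resolution 2.0 gave a monocyte share of 1.63, class II -0.077, class I 0.11, hypoxia 0.0049 and Fc receptors 0.025. Variable genes chosen within each library gave class II -0.089, IL-4 response 0.22, hypoxia 0.11 and Fc receptors 0.010. Clustering without list genes gave class II -0.051, interferon gamma -0.057, Fc receptors 0.0014 and cytotoxic genes 0.063 in CD8 cells. Classing cells by marker levels without clusters gave shares of -0.30 for macrophages, 0.74 for T cells, 0.95 for CD8 cells and 2.02 for NK cells, class II -0.12 and class I 0.096. It also gave cytotoxic genes 0.0075 and proliferation -0.13 in CD8 cells, proliferation -0.062 in NK cells, class II 0.064 in monocytes and interferon gamma -0.088 in type 1 DCs. TMM scaling moved the median of all macrophage genes from -0.11 to 0.02, and with it class II to -0.091, class I to 0.16, IL-4 response to 0.13, interferon gamma to 0.26, Arg1 to 0.084 and class II in type 2 DCs to 0.0090. Relative to all genes, class II stayed below and class I above under both scalings. Weighting cells equally gave class II -0.20, B2m -0.036 and, in CD8 cells, exhaustion 0.0076, proliferation -0.18 and Mcm4 -0.027, and interferon gamma -0.014 in migratory DCs. Thinning to 1000 UMIs gave class I -0.019, interferon gamma 0.050 and B2m -0.033, and in CD8 cells cytotoxic genes -0.25, exhaustion 0.060, Tnfrsf9 0.056, Tcf7 0.47, Birc5 -0.33, Hist1h2ak -0.49 and Mcm4 -0.50. Xist-only barcodes gave shares of -0.86 for macrophages, -0.45 for T cells and 0.48 for unnamed cells, class I 0.093, IL-4 response 0.084 and interferon gamma 0.33. Y-only barcodes gave shares of 5.03 for macrophages, 2.12 for T cells, 1.48 for CD8 cells, 0.0014 for regulatory T cells and -0.32 for mixed barcodes. Their lists were class II -0.17, class I -0.10 and interferon gamma -0.15, exhaustion 0.012 in CD8 cells, interferon gamma -0.28 and type I interferon -0.35 in type 1 DCs, -0.20 and -0.22 in type 2 DCs, and interferon gamma -0.32 in migratory DCs. Their genes were B2m -0.067, Arg1 0.26 and Retnla 0.23, and in CD8 cells Pdcd1 0.012, Penk 0.34, Hist1h2ak -0.52, Gzme 4.16, Gzmd 3.04, Gzmf 1.17 and Gzmc 0.35, on 24 control and 30 IL4 cells. Without the top 10% of doublet scores Arg1 was 0.015. Weighting the control clusters as in IL4 gave class II -0.0093, class I 0.18, interferon gamma 0.022, Il4ra -0.077, H2-DMb2 0.083 and H2-Ab1 0.024. By construction this shift comes from the mix of clusters. List genes were not kept out of the clustering, so their levels can themselves set that mix, and the cause is not shown. All myeloid clusters together gave class II -0.081, class I 0.090 and interferon gamma 0.049. Without each gene's highest barcode per library, Gzme was 0.16 and the cytotoxic list in CD8 cells 0.046, so 1 control barcode had set the sign of Gzme. Keeping mixed barcodes gave shares of 1.04 for T cells and 1.18 for CD8 cells and proliferation -0.22 in CD8 cells. A mixed limit of 10 per 10000 gave an NK share of 0.97, and one of 40 gave exhaustion -0.060 in CD8 cells. No type 1 DC class formed, and so gave no value, at resolution 0.5, with variable genes chosen within each library or without list genes, and no CD8 class formed with the mixed limit of 10. The number of cells limits the precision of the CD8 comparison, with 61 and 130 cells, and depth that of Smyd5, with 168 and 157 UMIs in macrophage-like cells. No paired analysis was possible because each group has 1 library.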

Other observations

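The division of barcodes by sex used here was chosen after the data were seen. The dissociation stress list was computed in the classes as a sign of handling. Its median was 0.23 in macrophage-like cells. The heat-shock gene Hspa1b went the other way there, at 405 CPM in the IL4 library and a log2 ratio of -1.33. In conventional DC type 1-like cells the median was 0.34 (0.30 to 0.36), in monocyte-like cells -0.12 (-0.14 to -0.11), in conventional DC type 2-like cells -0.08 (-0.09 to -0.05) and in CD8 T cell-like cells -0.06 (-0.18 to 0.02). The cytotoxic effector list, made of T and NK cell genes, had a median of 0.58 (0.35 to 0.64) in monocyte-like cells, with 0.59 in Xist-only and 0.13 in Y-only barcodes, beside the 0.49 in macrophage-like cells.

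In NK-like cells, hypoxia and glycolysis genes had a median log2 ratio of 0.29 (0.22 to 0.40), with 3 of 15 members higher and 0 lower, and 0.37 in Xist-only and 0.49 in Y-only barcodes. A subcluster of NK-like cells led by Vegfa, a hypoxia-induced gene, held 11 control and 86 IL4 cells. Neutrophil-like cells of the IL4 library, 163 against 412 in the control, had a hypoxia and glycolysis median of -0.53 (-0.62 to -0.45), with 5 of 15 members lower and 0 higher (-0.42 in Xist-only and -0.71 in Y-only barcodes), and an interferon gamma response median of -0.43 (-0.62 to -0.13), with 5 of 18 members higher and 7 lower, and with -0.38 in Xist-only and -1.36 in Y-only barcodes. Their NF-kB median was 0.40 (0.26 to 0.44), with 0.13 and 0.37. The within-sex values of neutrophil-like cells rest on 102 control and 56 IL4 Xist-only barcodes and on 113 and 19 Y-only ones. The class had medians of 3102 and 2559 UMIs. After thinning, 19.1% (17.2% to 21.1%) of control and 29.6% (27.9% to 31.3%) of IL4 macrophage-like cells had a UMI of Cd274, the gene of the checkpoint ligand PD-L1. In undivided T cells the thinned shares were 8.08% and 18.5%. Unthinned, they were 56.0% and 73.9% in macrophage-like cells. Innate lymphoid cell-like cells numbered 1 and 13, and gamma delta T cell-like cells 7 and 12.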
